A study of Mus musculus with 4 samples.

How the data were processed

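Total RNA of mouse liver was measured on Illumina whole-genome expression arrays. Per the labels, the 4 samples came from mice 2 months of age that had not been fasted, and 500 ng of RNA per sample was amplified into biotin-labelled cRNA. The 2 control livers carried floxed alleles of the gene for the phosphatase Shp2 and are labelled wild type, and the 2 knockout livers came from albumin-Cre-positive mice, in which Cre removes the floxed sequence in hepatocytes. All 4 arrays lay on 1 BeadChip, with the controls at neighbouring positions and the knockouts at the next positions, so that position and group cannot be told apart. Nothing in the labels states from how many mice each group's RNA came, and p-values therefore measure only the spread between these samples.

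The authors deposited a scanner table that holds, for each of 25697 probes, the mean bead intensity and a detection p-value per array. Intensity is on a linear scale; background had not been subtracted, and every array had the same mean intensity of 1186.5, so that the arrays had been scaled to a common mean before they were deposited. Rows with no probe identifier, 4 in number, were left out. The detection p-value deposited beside each intensity is, by Illumina's definition, a comparison of the probe with negative control beads. A further table deposited by the authors holds processed intensity on a linear scale, with 25.4% of values below 0 on control array 2 and medians of 31.58, 31.61, 31.62 and 31.63 on the 4 arrays; it ranked the probes of each array exactly as the scanner table did (Spearman correlation 1). The distributions of that table matched between arrays, while its background and normalization methods are not given in the sources used here; neither the scale nor the direction is in doubt, since the values are linear and rank as the scanner values do. It was used as an alternative only.

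The scanner intensities were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3. This function estimates background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe entered the test if its detection p was under 0.05 on at least 2 of the 4 arrays, which held for 12197 probes. Gene symbols came from the platform annotation, in which 23978 probes had 1 symbol, 0 had several and 1719 had none; 23962 of the probes matched the reference gene table of assembly GRCm38.p6 by gene number, and 0 symbols needed an update. Each gene was represented by its passing probe with the highest mean log2 intensity over all arrays, and probes with no symbol were tested as probes. This gave 9311 rows, made up of 8579 genes and 732 probes with no symbol.

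Knockout was compared with control by lmFit and eBayes of limma, two-sided, with the Benjamini-Hochberg adjustment over all 9311 rows. A gene was called changed at an adjusted p under 0.05. With 2 arrays per group the model had 2 residual degrees of freedom, to which eBayes added 3.375 from the other genes. Differences are knockout minus control on the log2 scale, with the standard error (SE) from the model. Where a probe was not above background on both arrays of a group, only a bound is given, written as at least N-fold. It sets the mean log2 value of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among detected probes of that array. The number of arrays limits the precision.

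Before the data were examined, 33 gene lists were fixed, covering pathways of the liver, Shp2 signalling and markers of other cell types. For each list the members are also given adjusted over the list alone. The 31 lists with at least 5 measured members were tested as sets with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each with its own Benjamini-Hochberg adjustment. The genes named in the text were also fixed by a rule before the data were examined. They are Ptpn11, the gene for Shp2; the 12 called genes with the largest difference in each direction whose knockout arrays both lay on the same side of both control arrays; up to 4 members of each list with the smallest p; 9 genes of bile acid metabolism and its feedback whatever their result; and Xist with the Y-linked genes as a check of sex. Other genes named below were chosen after their values were seen, and are marked as such.

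The fit was tested on simulated arrays, with 200 of 9311 rows changed in each of 20 simulations of 2 arrays against 2. Row means were those of the real genes. Each row's variance was drawn at random from the spread of variances that eBayes had fitted over all rows, with independent normal noise. The fit called 5.30% of genes changed by 2-fold, 81.4% of those changed by 4-fold and 94.9% of those changed by 8-fold, and 5.18% of its calls were unchanged genes. Such arrays follow the model that eBayes assumes, so the 5.18% does not test that model on the real data. On simulated lists camera with the preset correlation found 100% of the lists shifted by 0.7 on the log2 scale and 0.4% of the unshifted lists. Those lists held random genes that varied independently. In the real lists that camera called shifted, the estimated correlation ran from 0.12 (stellate and matrix) to 0.56 (cholesterol synthesis). The 0.4% is therefore not a false rate for the real lists.

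Alternatives fixed before the data were examined were quantile normalization without background correction, scaling to a common median, the deposited processed intensities, no filter on detection, detection on all 4 arrays, a detection p under 0.01, the mean of a gene's probes, every probe tested on its own, an offset of 50, eBayes with an intensity trend and a robust prior, an adjusted p under 0.10, an added requirement of a 2-fold change, the other set tests, and leaving out each array in turn. Where an array was left out, the lone sample of its group was assumed to vary as the other group did. Tests of explanations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, with 10000 random draws or 100000 permutations, and figures were drawn with Matplotlib 3.10.9.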

Results

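Gene expression was measured in liver tissue of 4 mouse samples, 2 floxed controls and 2 hepatocyte knockouts of Shp2, a phosphatase that relays signals from receptor tyrosine kinases to the Ras and ERK pathway. In the scanner table, whose arrays had been scaled to a common mean, the median intensity was 251 and 262 units on the control arrays. On the knockout arrays it was 242.2 and 256.6. Of 25697 probes, 11990 and 11542 were detected above background in the controls, and 12328 and 11809 in the knockouts. Across genes, the normalized log2 values correlated at r = 0.984 between the controls and at r = 0.982 between the knockouts, while the 4 pairs of a control with a knockout gave r between 0.964 and 0.974; genes are not independent replicates. The design poses the question of which liver transcripts differ when hepatocytes lack Shp2.

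Ptpn11, the gene for Shp2, was measured by the probe ILMN_3001598 at log2 intensities of 12.75 and 12.85 in the control livers and 11.38 and 11.56 in the knockout livers. The difference was −1.33 (SE 0.18, n = 2 per group), 2.51-fold lower in knockout, and both knockout values lay below both control values. In limma's test over all rows its adjusted p was 0.0599, just short of the threshold. The other detected probes of Ptpn11 differed by −1.13 and −1.26, and a further probe was not above background on any array. The position of these probes relative to the floxed exon was not analysed here, and a probe outside the deleted part would not show the deletion. Over the 10 alternatives that kept all arrays its adjusted p ran from 0.00115 to 0.0921, and it passed the threshold under 5 of them. Among sex-specific genes, the Y-linked Eif2s3y was detected in all samples with a difference of 0.08 (SE 0.21), and Kdm5d with −0.19 (SE 0.31). Uty differed by −0.97 (SE 0.25, adjusted p = 0.167) and was detected on both control arrays and 1 of the 2 knockout arrays; adjusted over the list alone it was the 1 lower gene of the 3 measured. Xist was not above background on any array. With the Y-linked Eif2s3y and Kdm5d detected on every array, this check showed no difference in sex between the groups. Whether the Xist probe can detect its transcript was not tested.

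**Figure D1:**
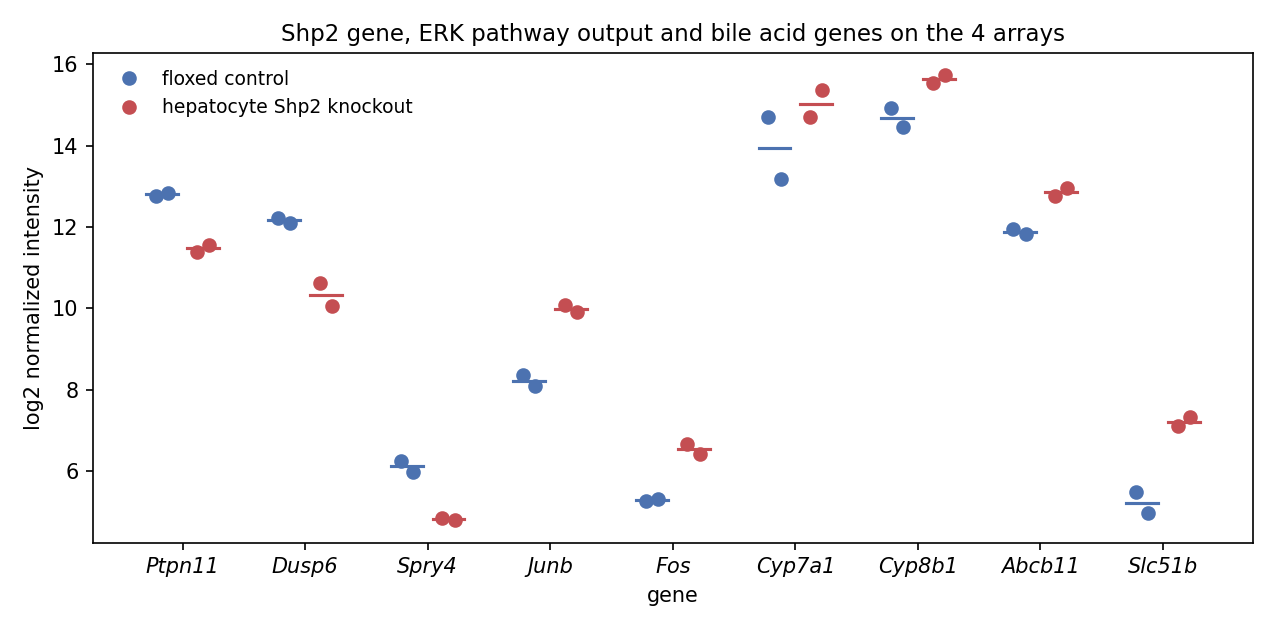
Normalized log2 intensity (vertical axis) of 9 genes (horizontal axis) on each array, with floxed control in blue and hepatocyte Shp2 knockout in red; points are single arrays and bars the mean of 2 arrays, and Spry4 in knockout and Fos and Slc51b in control were not above background. Ptpn11 lies at 12.75 and 12.85 in control against 11.38 and 11.56 in knockout, and the control values of Cyp7a1, 14.71 and 13.18, overlap with its knockout values, 14.70 and 15.37.

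Expression of 68 genes changed between knockout and control liver, 39 higher and 29 lower in the knockout, each with a fitted difference of at least 2-fold. Genes with the largest fitted rises included Gal3st1, which encodes a sulfotransferase that makes sulfatide (difference 3.12, SE 0.37, adjusted p = 0.0441), Spon2, a secreted matrix protein (2.81, SE 0.28, adjusted p = 0.0324), Nr1d1, the clock repressor Rev-erb alpha (2.37, SE 0.21, adjusted p = 0.0244), and Csad, an enzyme of taurine synthesis (2.35, SE 0.23, adjusted p = 0.0311). Spink1, a trypsin inhibitor, rose by 2.75 (SE 0.25) and was detected on 1 of the 2 control arrays. The other 7 of the 12 largest fitted rises were not above background in control liver, so that only bounds hold. Psmc3ip, a cofactor of meiotic recombination, was at least 7.13-fold higher, the zinc transporter gene Slc39a5 at least 5.30-fold, Trappc12 at least 4.64-fold, Tinag at least 4.54-fold, the aldo-keto reductase gene Akr1c18 at least 4.05-fold, the prostaglandin D synthase gene Ptgds at least 3.50-fold and Lrrc24 at least 3.02-fold.

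Among the largest falls was that of Scara5, a ferritin receptor, with a fitted difference of −5.37 on the log2 scale (SE 0.39, adjusted p = 0.0136) and 1 of the 2 knockout arrays above background, so that its size is uncertain. Hsd3b5, a steroid reductase gene expressed mainly in male liver, fell by 4.19 (SE 0.32, adjusted p = 0.0163). Lpin1, which encodes a phosphatidate phosphatase, fell by 3.08 (SE 0.19), the acyl-CoA thioesterase gene Acot4 by 3.06 (SE 0.20), the glucocorticoid-induced co-chaperone gene Fkbp5 by 2.72 (SE 0.25) and Thrsp, a promoter of lipogenesis, by 2.70 (SE 0.19). Camk2b, a calcium-dependent kinase gene, was not above background in knockout and was at least 16.2-fold lower, Twistnb at least 6.89-fold, Fam107a at least 5.02-fold and Vmn1r65 at least 4.35-fold lower. Of the 12, only Epm2aip1, Tom1l2 and Twistnb had a further detected probe. That of Twistnb was below background in knockout too and could not be compared. The 2 genes that could be compared both disagreed. The called probe of Epm2aip1 was at least 10.2-fold lower while a probe detected on all 4 arrays differed by −0.06. Tom1l2 fell by 2.75 on the called probe (1 of 2 knockout arrays detected). It differed by 0.35 on another, which was detected on 1 of the 2 control arrays. For the rest of the 12, agreement between probes could not be checked. Alongside these genes, macrophage markers had a median difference of 0.72, endothelial markers of 0.01 and hepatocyte markers of −0.05.

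At an unadjusted limma p under 0.05 there were 1403 genes, 16.4% of those tested, 806 higher and 597 lower. Most calls were lost when any array was left out. In those fits 1 group holds only 1 sample, so that lost calls reflect the small design as well as unstable differences. The 45 called genes named here kept their direction in each of those fits. Both knockout values of each gene lay on 1 side of both control values. A reversal was therefore hardly possible, and the kept direction says little about stability. From the deposited processed intensities 16 genes were called, all among the 68, with 5 higher and 11 lower.

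**Figure D2:**
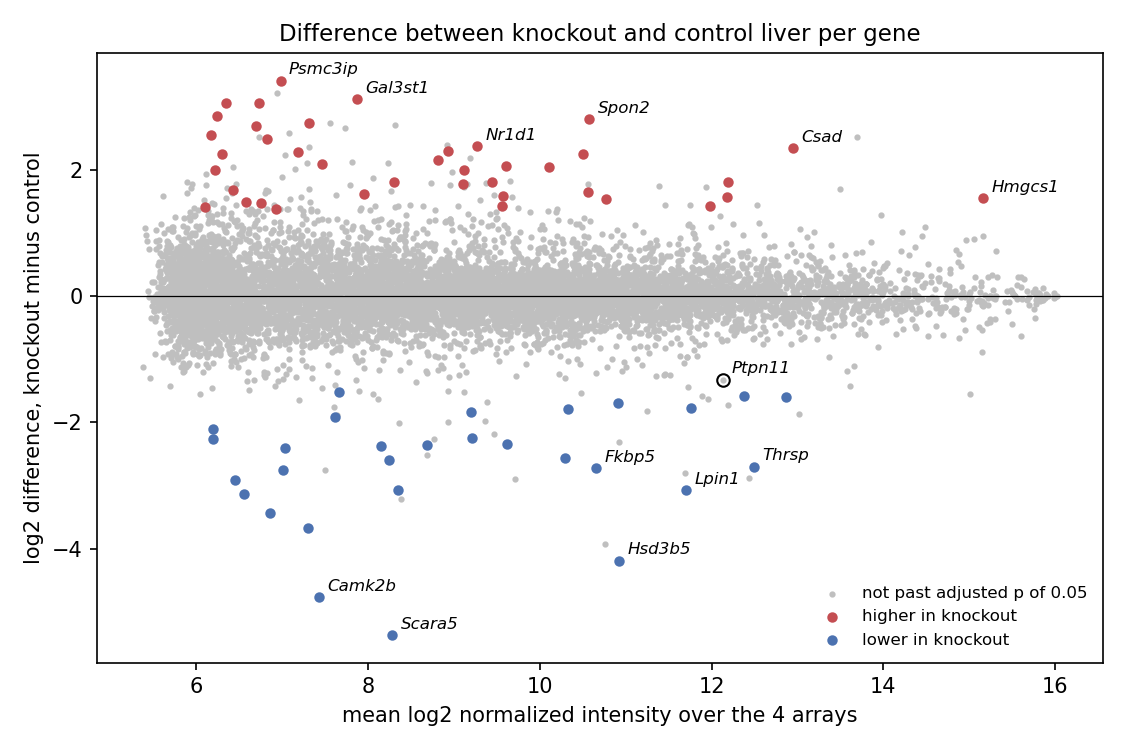
Log2 difference, knockout minus control (vertical axis), against the mean log2 normalized intensity over the 4 arrays (horizontal axis); each point is 1 of 8579 genes, with the 39 called higher in red, the 29 called lower in blue and the rest in grey. Named points include Scara5 at −5.37 and Gal3st1 at 3.12, and Ptpn11, circled, lies at −1.33 among the genes short of the threshold.

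Among the ERK pathway output genes, which report activity of the cascade below Shp2, Junb rose by 1.78 (SE 0.20, adjusted p = 0.0424) and the other 10 of 11 measured genes did not pass. The ERK phosphatase gene Dusp6 differed by −1.83 (SE 0.25, adjusted p = 0.0579), 3.55-fold lower, and by −2.12 on a further probe; with every probe tested on its own the adjusted p was 0.0732 and 0.0372 for these. Of the feedback inhibitor genes of the pathway, Spry4 was not above background in knockout and at least 1.25-fold lower (adjusted p = 0.0673), and Spred1 differed by −1.13 (SE 0.29). The immediate early gene Fos was not above background in control and at least 1.60-fold higher (adjusted p = 0.0737). Adjusted over the list alone, 2 were higher (Junb and Fos) and 3 lower (Dusp6, Spry4 and Spred1, the last chosen after its value was seen). The list as a whole was not shifted in 1 direction (median 0.00, camera adjusted p = 0.984). Its median and mean were just below 0 and camera's direction was up. The test of fry for change in either direction did find this list changed (adjusted p = 0.00188). None of the 15 measured Shp2 signalling partners passed over all rows (median 0.24, adjusted p = 0.109). Irs2, an insulin receptor substrate, differed by 1.97 (SE 0.29, adjusted p = 0.0653) and was the 1 member higher adjusted over the list alone.

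Genes of bile acid transport included 1 called gene of 13 measured, Slc51b, a subunit of the basolateral bile acid exporter, which was not above background in control and at least 2.56-fold higher in knockout (adjusted p = 0.0482). Over the alternatives that kept all arrays and tested Slc51b, its limma adjusted p ran from 0.0153 to 0.134. The canalicular bile salt pump gene Abcb11 differed by 0.97 (SE 0.19, adjusted p = 0.116), the phospholipid transporter gene Abcb4 by 0.86 (SE 0.22) and Ephx1, an epoxide hydrolase also linked to bile acid uptake, by 0.78 (SE 0.22). These 4 were higher and 0 were lower adjusted over the list alone, while the uptake transporter gene Slc10a1 differed by 0.15 (SE 0.22). Of 14 measured bile acid synthesis genes 0 passed over all rows and 0 adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of the pathway, differed by 1.09 (SE 0.54, adjusted p = 0.40), with control values of 14.71 and 13.18 and knockout values of 14.70 and 15.37, so that the groups overlapped. Cyp8b1, the sterol 12-alpha-hydroxylase gene, differed by 0.94 (SE 0.23, adjusted p = 0.161), Hsd3b7 by 0.89 (SE 0.20), Cyp2c70 by 0.47 (SE 0.18), Cyp27a1 by 0.29 (SE 0.20) and Cyp7b1 by −1.19 (SE 0.51). In the list of bile acid sensing and FGF receptor signalling 0 of 10 passed by either adjustment. Nr1h4, the bile acid receptor FXR, differed by −0.12 (SE 0.19), Klb, the co-receptor beta-Klotho, by 0.38 (SE 0.23), Fgfr2 by 1.01 (SE 0.25), the xenobiotic receptor gene Nr1i3 by −0.80 (SE 0.21) and the hormone gene Fgf21 by 2.10 (SE 0.63). Fgfr4 and Nr0b2 were each detected on 1 array and were not tested. None of these 3 lists was shifted in 1 direction (camera adjusted p of 0.427, 0.461 and 0.974 for transport, synthesis and sensing). The test of fry for change in either direction found all 3 changed (adjusted p of 0.00188, 0.0274 and 0.0124 in the same order).

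Cholesterol synthesis genes were higher in knockout as a group, with a median of 0.83 and all 18 measured genes above 0 (camera adjusted p = 5.2e-06). The call was lost with an estimated correlation (adjusted p = 0.844). Hmgcs1, which encodes the HMG-CoA synthase of the pathway, rose by 1.55 (SE 0.19, adjusted p = 0.0443), and the other 17 did not pass over all rows. After quantile normalization Hmgcs1 had the same value, 15.94, on both knockout arrays (SD 0), near the top of the intensity range. The size of its difference and its SE are therefore uncertain. Mvd differed by 1.57 (SE 0.33), Cyp51 by 1.26 (SE 0.28) and Hsd17b7 by 0.93 (SE 0.22); adjusted over the list alone these 4 were higher and 0 were lower. The median was 0.43 without knockout replicate 2. In the same samples the medians of macrophage, stellate and matrix, and red blood cell genes were 0.72, 0.44 and 1.24, and that of hepatocyte markers −0.05. Of 17 fatty acid synthesis genes, Thrsp fell and 16 did not pass. The glycolytic enzyme gene Pklr differed by −1.17 (SE 0.27) and the lipogenic regulator gene Srebf1 by −1.23 (SE 0.29), whereas the elongase gene Elovl5 differed by 0.90 (SE 0.23). Elovl5 was the 1 higher and Thrsp, Pklr and Srebf1 the 3 lower adjusted over the list alone, and the list was not shifted (median −0.03, adjusted p = 0.461). None of the 19 fatty acid oxidation genes passed by either adjustment (median 0.07, adjusted p = 0.576), with Cyp4a14, a fatty acid hydroxylase gene, at 2.51 (SE 0.51, adjusted p = 0.126).

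Genes of gluconeogenesis and glucose use had a median of −0.15, and 0 of 13 passed over all rows (camera adjusted p = 0.0772). Adjusted over the list alone 0 were higher and 3 were lower: the glucose 6-phosphate transporter gene Slc37a4 (−1.51, SE 0.31), the liver glycogen synthase gene Gys2 (−0.99, SE 0.21) and Foxo1, a transcription factor restrained by insulin (−0.77, SE 0.18). In the circadian clock list Nr1d1 rose and the other 14 of 15 did not pass (median −0.33, adjusted p = 0.382). Per2 differed by −1.26 (SE 0.21, adjusted p = 0.0876), Ciart by −1.0 (SE 0.27), and Dbp by 0.68 (SE 0.19, chosen after its value was seen), while Hlf was not above background in knockout and at least 1.52-fold lower. Nr1d1 and Dbp were the 2 higher and Per2, Ciart and Hlf the 3 lower adjusted over the list alone.

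The oxidative stress response list was higher in knockout, with a median of 0.68 and all 14 measured genes above 0 (camera adjusted p = 2.8e-06); the call was lost with an estimated correlation (adjusted p = 0.844). The glutathione transferase gene Gsta1 rose by 2.06 (SE 0.22, adjusted p = 0.0345), and 13 did not pass over all rows. Osgin1 differed by 1.14 (SE 0.20), the haem oxygenase gene Hmox1 by 1.11 (SE 0.19) and the autophagy receptor gene Sqstm1 by 1.02 (SE 0.19). Of the 14, 7 were higher and 0 lower adjusted over the list alone. Macrophage markers, described with the other cell types, were higher in the same samples (median 0.72). In the drug metabolism list 0 of 22 passed by either adjustment (median 0.02, adjusted p = 0.947). None of 18 endoplasmic reticulum stress genes passed over all rows (median −0.16, adjusted p = 0.461); adjusted over the list alone Trib3 was higher (1.05, SE 0.23) and Atf4 lower (−2.19, SE 0.47). Of 11 heat shock genes 0 passed by either adjustment (median −0.27, adjusted p = 0.461).

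Male-biased liver genes were lower in knockout as a group (median −0.60, 11 of 13 below 0, camera adjusted p = 0.0200), a call lost with an estimated correlation (adjusted p = 0.844), while hepatocyte markers had a median of −0.05 and macrophage markers of 0.72. Hsd3b5 fell and 12 did not pass over all rows. Selenbp2 differed by −1.63 (SE 0.32) and Susd4 by −2.51 (SE 0.53), while Cyp4a12b, an arachidonate hydroxylase gene, differed the other way, by 1.69 (SE 0.25, adjusted p = 0.0668). Adjusted over the list alone 4 were lower (Hsd3b5, Selenbp2, Susd4 and Cyp2d9) and 2 higher (Cyp4a12b and Elovl3), Cyp2d9 and Elovl3 being chosen after their values were seen. The list was no longer shifted without control replicate 2 (median −0.36, adjusted p = 0.0940) or without knockout replicate 1 (median −0.26, adjusted p = 0.0641); over the 4 fits that left out an array the adjusted p ran from 0.000617 to 0.0940. The call was also lost with the mean of a gene's probes (−0.57, adjusted p = 0.0613) and with every probe on its own (−0.53, adjusted p = 0.0654), in a range of 0.000520 to 0.0654 over the other alternatives. Of 9 female-biased genes 0 passed over all rows, and 3 were higher and 0 lower adjusted over the list alone: Cyp4a14, Cyp2b9 (2.66, SE 0.69, detected on 1 of the 2 control arrays) and Acot3 (1.20, SE 0.33). That list was not shifted (median 0.33, adjusted p = 0.470). None of the 9 growth hormone and STAT5 targets passed by either adjustment (median 0.32, adjusted p = 0.461), with Socs2, a feedback inhibitor of growth hormone signalling, at 1.34 (SE 0.31).

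**Figure D3:**
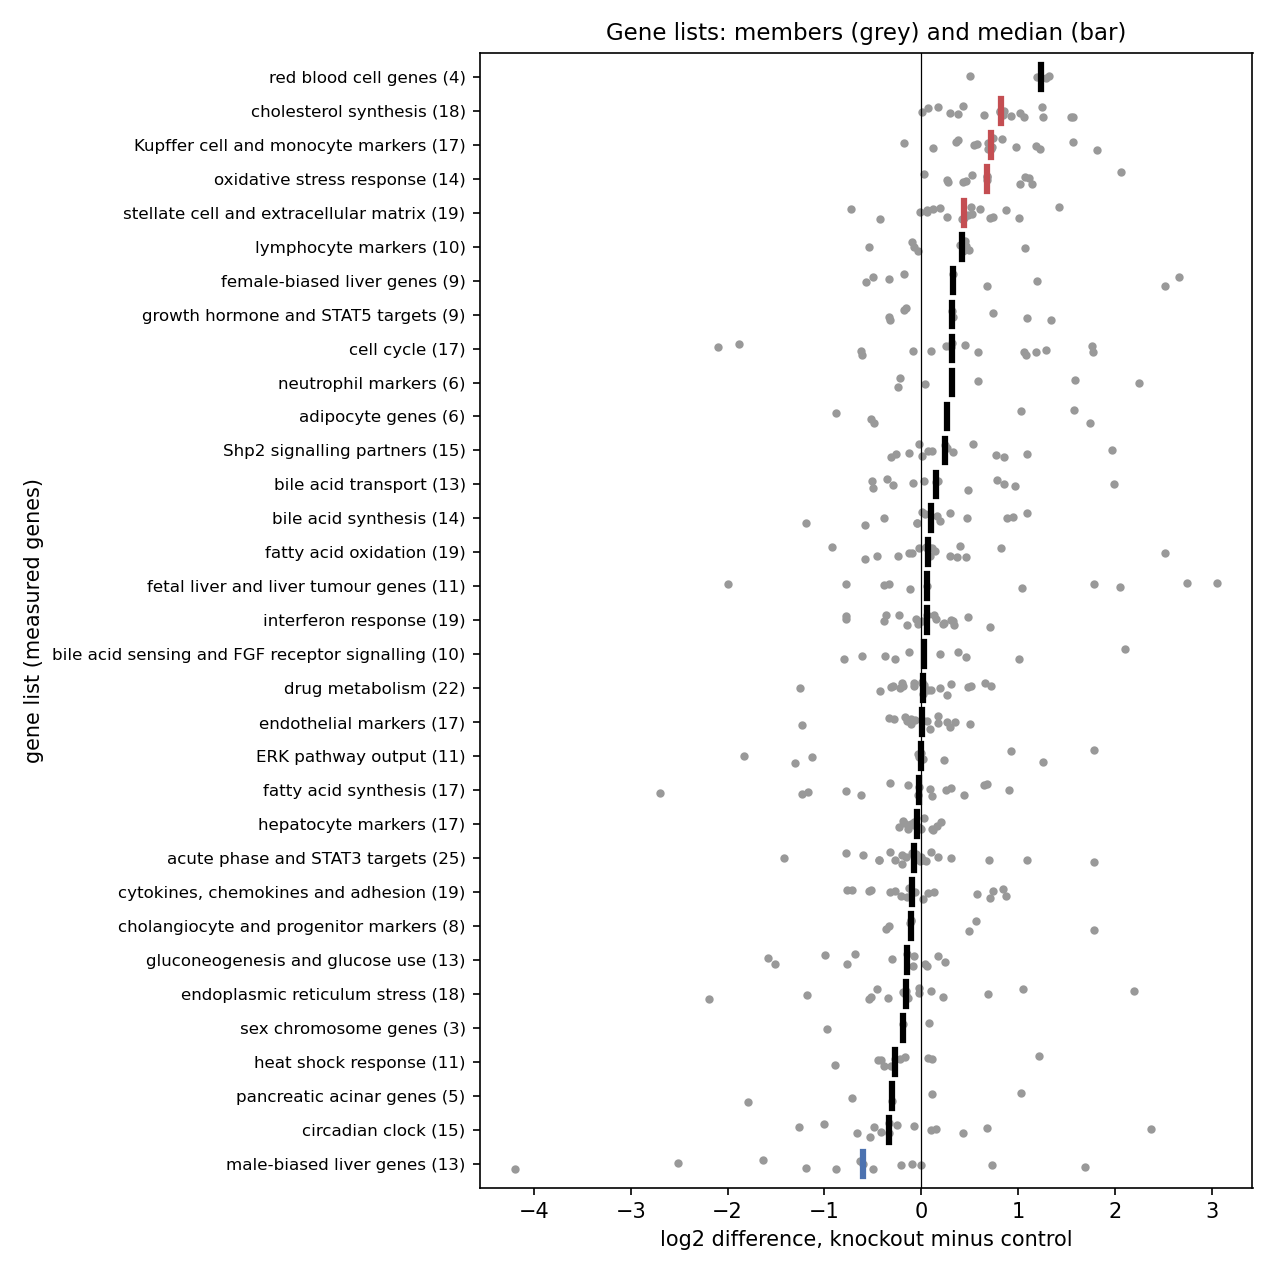
Log2 difference, knockout minus control (horizontal axis), of the measured members of each of 33 gene lists (vertical axis, with the number measured in brackets); grey points are genes and bars the list median, red or blue where camera with a preset correlation found the list shifted up or down and black otherwise. The 4 lists in red have medians of 0.83, 0.72, 0.68 and 0.44, and male-biased liver genes, in blue, have −0.60.

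The list of Kupffer cell and monocyte markers was higher in knockout (median 0.72, 16 of 17 above 0, camera adjusted p = 5.5e-05), and so was that of stellate cells and extracellular matrix (median 0.44, 16 of 19 above 0, adjusted p = 0.0138); both calls were lost with an estimated correlation (adjusted p = 0.844 for each). No gene of either list passed over all rows. There were 4 macrophage genes higher and 0 lower adjusted over the list alone: the lysozyme gene Lyz2 (1.82, SE 0.41), Timd4, a receptor of resident Kupffer cells (1.57, SE 0.37), the galectin gene Lgals3 (1.22, SE 0.29) and the endotoxin co-receptor gene Cd14 (1.18, SE 0.29). The matrix genes Lum (1.42, SE 0.26) and Col4a1 (1.01, SE 0.21) were the 2 higher adjusted over the list alone, with 0 lower. Control replicate 2 lay below control replicate 1 in both lists, with a median of replicate 2 minus replicate 1 of −0.76 for macrophage and −0.39 for matrix genes. Without control replicate 2 the macrophage median was 0.37 (adjusted p = 0.0122; range over arrays left out 8.5e-10 to 0.0122). The matrix list was no longer shifted without control replicate 2 (0.27, adjusted p = 0.165) or without knockout replicate 2 (0.40, adjusted p = 0.0785), the range being 0.000617 to 0.165. Quantile normalization without background correction gave smaller medians for both lists, 0.43 and 0.17, and the matrix median was 0.29 with no filter on detection.

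Among 6 measured neutrophil genes, S100a8, which encodes a subunit of calprotectin, was not above background in control and at least 2.97-fold higher in knockout (adjusted p = 0.0227). Its partner S100a9 was at least 1.47-fold higher with an adjusted p of 0.0600, and adjusted over the list alone these and Csf3r were the 3 higher, with 0 lower; the list was not shifted (median 0.31, or 0.30 with genes below background at their bound, adjusted p = 0.104). Of 10 lymphocyte markers, the B cell receptor gene Cd79b (at least 1.64-fold higher, adjusted p = 0.101) was the 1 higher adjusted over the list alone (median 0.42, adjusted p = 0.427). All 4 measured red blood cell genes lay above 0 (median 1.24), too few to test as a set. Hba-a1 differed by 1.29 (SE 0.36), Hbb-bt by 1.19 (SE 0.23), Slc4a1 by 1.32 (SE 0.51, detected on 1 of the 2 control arrays) and Alas2 by 0.50 (SE 0.18); 0 passed over all rows and 4 were higher adjusted over the list alone. The 17 endothelial markers had a median of 0.01 (adjusted p = 0.974), a mean of −0.03, and 0 passed by either adjustment; control replicate 2 lay below control replicate 1 here too (median −0.74). The 17 hepatocyte markers had a median of −0.05 (adjusted p = 0.758) and 0 passed by either adjustment. Of 8 cholangiocyte and progenitor markers 0 passed over all rows, and the tetraspanin gene Tspan8 (at least 1.98-fold higher) was the 1 higher adjusted over the list alone; the median was −0.10, while the mean of 0.23 and camera's direction were positive (adjusted p = 0.758). In the pancreatic acinar list the elastase gene Cela1 fell by 1.78 (SE 0.18, adjusted p = 0.0341) and 4 of 5 did not pass (median −0.30, adjusted p = 0.461). Of 6 adipocyte genes, Pparg, a lipid-storage nuclear receptor, rose by 1.58 (SE 0.19, adjusted p = 0.0441), and the lipoprotein lipase gene Lpl differed by 1.75 (SE 0.23, adjusted p = 0.0506). These 2 were the higher ones adjusted over the list alone (median 0.27, adjusted p = 0.461).

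In the list of fetal liver and liver tumour genes Akr1c18 and Spink1 rose and 9 of 11 did not pass over all rows (median 0.06, camera adjusted p = 0.242). Ly6d differed by 2.05 (SE 0.45, detected on 1 of the 2 control arrays). Adjusted over the list alone 5 were higher (Akr1c18, Spink1, Ly6d, Tspan8 and Golm1) and 2 lower (Gpc1 at −2.00 and Lcn2 at −0.78), with Golm1, Gpc1 and Lcn2 chosen after their values were seen. Among 17 cell cycle genes the ribonucleotide reductase gene Rrm2 was at least 2.74-fold lower (adjusted p = 0.0261) and not above background in knockout, and 16 did not pass over all rows. The replication helicase genes Mcm3 (at least 1.06-fold higher) and Mcm6 (1.29, SE 0.32) lay above control and the cell cycle inhibitor gene Cdkn1a below it (−1.88, SE 0.37). Adjusted over the list alone 5 were higher (Mcm2, Mcm3, Mcm5, Mcm6 and Top2a) and 3 lower (Rrm2, Cdkn1a and Tk1), and the list was not shifted (median 0.32, or 0.31 with genes below background at their bound, adjusted p = 0.461); Mcm2, Mcm5, Top2a and Tk1 were chosen after their values were seen. None of 25 acute phase and STAT3 target genes passed over all rows (median −0.08, adjusted p = 0.499); adjusted over the list alone the inhibitor gene Socs3 was higher (1.78, SE 0.30) and the serum amyloid gene Saa4 lower (−1.42, SE 0.19, adjusted p over all rows 0.0539). Of 19 genes for cytokines, chemokines and adhesion and of 19 interferon response genes, 0 passed by either adjustment, with medians of −0.09 and 0.06 (adjusted p = 0.974 and 0.908); the mean of the former, 0.01, and camera's direction were positive.

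Over all lists, camera with a preset correlation found 5 of 31 shifted, 4 up and 1 down. With an estimated correlation 0 were shifted (smallest adjusted p = 0.844). The directional test of fry found 0 (smallest adjusted p = 0.201) and its test for change in either direction 16. Those included male-biased genes (fry adjusted p = 0.0198) and oxidative stress (0.0263). They did not include cholesterol synthesis (0.0757), stellate and matrix (0.0757) or macrophage genes (0.169). Lists described above as not shifted were judged by camera, which looks for a shift in 1 direction.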

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

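Among the 732 tested probes that carry no gene symbol in the annotation, 3 were called higher in knockout liver than in control liver and 3 lower, a signal outside the genes described above. The 3 higher probes were ILMN_1255416 (2.79, SE 0.22), ILMN_3108770 (2.19, SE 0.19) and ILMN_2692554 (not above background in control and at least 2.05-fold higher), with limma adjusted p of 0.0163, 0.0227 and 0.0276. The 3 lower probes were ILMN_2449449 (−2.55, SE 0.18), ILMN_2455192 (−3.07, SE 0.32), each of these detected on 1 of the 2 knockout arrays, and ILMN_2900431 (−1.69, SE 0.22), with adjusted p of 0.0136, 0.0341 and 0.0494. Their genes were not analysed here and no explanation was tested for them.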

How the results depend on the processing

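With 2 arrays per group, the count of called genes depended on the processing. Against 68 called genes (39 higher, 29 lower), quantile normalization without background correction gave 292 (174 and 118), the deposited intensities 16 (5 and 11), every probe on its own 41 (19 higher), the offset of 50 gave 144 (82 and 62), the intensity trend with a robust prior 331 (202 and 129) and an adjusted p under 0.10 gave 158. Leaving out an array gave 0 to 23 called (0 to 11 higher and 0 to 12 lower); those fits rest on 3 samples. Of the 68, 63 were shared with the calls of quantile normalization alone, 37 with every probe, 67 with the offset of 50 and 68 with the trend; the cause of these differences was not tested. Ptpn11 was past the threshold, at −1.27 with quantile normalization alone, −1.32 with an offset of 50 and −1.33 with detection on all 4 arrays, a detection p under 0.01 or the trend (adjusted p from 0.00115 to 0.0921 over the 10 alternatives). It was between −1.42 and −1.25 with an array left out (adjusted p 0.148 to 0.241). Detection on all 4 arrays and at p under 0.01 tested fewer rows. The number of shifted lists, 5, was 9 with no filter on detection, 5 to 8 with an array left out, 0 with an estimated correlation, 0 with fry's directional test and 16 with its test in either direction. Male-biased genes were not shifted with the mean of a gene's probes (−0.57) or every probe on its own (−0.53), the adjusted p running from 0.000520 to 0.0654. The 45 called genes named here kept their direction under every alternative that tested them, with 374 results past the threshold and 57 not. Genes with no probe detected on all 4 arrays had no result under that filter. Of the 68 calls, 44 were shared with that filter. With an array left out the direction was also kept, where a reversal was hardly possible. The 81 named genes that were not called stayed short of the threshold 684 times and passed it 108 times. With an array left out 4 genes with differences near 0 took both signs: Nr1h4 (from −0.25 to 0.00028), Slc10a1 (from −0.034 to 0.33), Kdm5d (from −0.61 to 0.24) and Eif2s3y (from −0.059 to 0.21). After scaling to a common median the median of all rows was 0.09. No paired analysis was possible because the control labels carry no replicate numbers. Signal over background limits genes near the floor, for which only bounds hold.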

Other observations

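Ppp1r3b and Ppp1r3c, which encode subunits that target protein phosphatase 1 to glycogen, fell by 2.35 (SE 0.27) and 1.61 (SE 0.19), with limma adjusted p of 0.0426 and 0.0441. Tsc22d3 and Ddit4, both induced by glucocorticoids, fell by 1.58 (SE 0.18) and 2.25 (SE 0.27), and further probes of Tsc22d3 and of the growth factor gene Fgf1 differed by −2.08 and −2.70. Fgf1 itself fell by 1.69 (SE 0.21, adjusted p = 0.0494). These genes were chosen after their values were seen.

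Called genes that rose and lie outside the gene lists included the membrane protein gene Tmem98 (2.30, SE 0.18), the oxysterol-binding protein gene Osbpl3 (2.29, SE 0.24, detected on 1 of the 2 control arrays), the thyroxine-binding globulin gene Serpina7 (2.25, SE 0.24), the tetraspanin gene Cd9 (1.80, SE 0.20), the annexin gene Anxa5 (1.57, SE 0.18), the transcription regulator gene Lmo2 (1.99, SE 0.25) and the hedgehog ligand gene Ihh (1.49, SE 0.19, detected on 1 of the 2 control arrays). They were chosen after their values were seen. The ribosomal protein gene Rpl29, also chosen after its values were seen, fell by 1.78 (SE 0.20) on its brightest probe and differed by −5.31 on another, which was detected on 1 of the 2 knockout arrays.

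All tests of explanations in this part were chosen after the result was seen, except that of neighbouring called genes, which was set before its result was seen. The demand that the result for resident Kupffer cell genes also hold without control replicate 2, the count of probes that moved over 2 times as much and the omission of probe pairs below background in the same group were added once the first values were known. The real grouping of the 4 samples gave 68 called genes and the other 2 splits gave 0 and 0, with 228 and 217 genes at an unadjusted limma p under 0.05; these splits are too few for a share under 0.05.

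Nr1d1 rose while Fkbp5, Tsc22d3, Ddit4 and Lpin1 fell, a pattern that different times of day at tissue collection or a lower glucocorticoid exposure of the knockout mice could give. Across 14 measured clock genes the difference had a Spearman correlation of −0.304 with the order of their daily peaks (permutation p = 0.292), and Nr1d1 was the only called gene among them, so that a time difference stays open. All 16 measured glucocorticoid targets had a median of −0.38, below that of each of 10000 random lists matched on mean expression, but they include the 3 called lower, in which the pattern was seen; the other 13 had a median of −0.09, at percentile 17.0. Neither explanation is excluded, and an effect of the Shp2 deletion itself stays open and untested.

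The tested probes of 11 called genes were not above background in control and those of 7 not in knockout, patterns that differences in genetic background between the mice or sequence variants under probes might give. Of the 68 called genes, 8 had another called gene within 10 tested genes on the chromosome (Rrm2 with Trappc12, Fgf1 with Spink1, Tinag with Gsta1 and Serpina7 with Tsc22d3), against a median of 10 in 10000 random draws (permutation p = 0.735). Clustering beyond chance was therefore not seen, but small or scattered segments stay open. Of the 20 genes flanking Ptpn11, 0 were called, which says little, since only 68 of all 8579 tested genes were. Of 15 called genes with a further detected probe, 3 had only probes not above background in the same group, which cannot be compared; of the other 12, 3 (Tom1l2, Epm2aip1 and Rpl29) had a probe that moved by under 50% as much, over 2 times as much or the other way, with an exact upper 95% limit of 57.2%. Variants under single probes thus stay open, as does an effect of the Shp2 deletion, which was not tested apart from these.

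The macrophage marker list was higher in knockout liver. A smaller share of hepatocytes would raise the markers of other cell types alike, but the macrophage median exceeded the endothelial median by 0.718 (permutation p = 0.00024, across 34 genes, which are not independent replicates), although the stellate and matrix (0.44), lymphocyte (0.42) and neutrophil (0.31) medians also lay above 0 and a part in these is not excluded. Whether the low values of control replicate 2 are the whole source cannot be told. The median without it was 0.374, but that value rests on 1 control. In this list the controls differed from each other by more, with a median of replicate 2 minus replicate 1 of −0.76. The call is also lost with an estimated correlation. More residual blood stays open: 8 genes of resident Kupffer cells, which blood does not bring, had a mean of 0.699 (95% bootstrap interval over genes 0.37 to 1.02), but without control replicate 2 the mean was 0.24 (−0.16 to 0.59), and the 4 measured red blood cell genes lay above control. An effect of the Shp2 deletion itself stays open and was not tested apart from these.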
